A study of Arabidopsis thaliana with 96 samples.

How the data were processed

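RNA was measured on 96 Affymetrix ATH1 arrays, single-colour arrays on which each transcript is read by a set of probes. The cells came from roots of Arabidopsis thaliana seedlings of the Columbia ecotype, harvested 5 to 7 days after germination. Per the labels, roots were turned into protoplasts and cells carrying a green fluorescent protein (GFP) reporter were sorted. WER::GFP marked the epidermis, COR::GFP the cortex, SCR::GFP the endodermis and WOL::GFP the stele, the vascular core of the root. Each cell type thus has its own reporter and sorts. A difference between reporter lines or sorts cannot be told apart from one between cell types. Seedlings stayed on standard medium for 1 h or 48 h, or were moved to medium with 140 mM NaCl for 1, 3, 8, 20, 32 or 48 h. Crossing 4 cell types with 8 conditions gives 32 groups of 3 arrays each. The labels do not say whether the replicates came from separate cultures, so the p-values describe the spread between these samples, which may be technical in part.

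Per the labels, RNA was amplified in 1 cycle and hybridised as biotin-labelled cRNA. The deposited values are log2 expression values that the authors made with GCRMA, which corrects background by probe sequence, normalizes across arrays and summarises each probe set. The submitters' processing notes name Affymetrix Expression Console and GCRMA without versions. The scale was checked on the values, which fit log2 and gave array medians between 4.50 and 4.96 over all probe sets. No further scaling was applied before the comparisons. The files give no detection calls or counts, so signal near an unknown background limits the precision beside the number of arrays.

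Probe sets were named from the platform annotation of August 2016, and symbols were updated by Entrez ID to the TAIR10.1 gene table, which was used for names only. Of 22810 probe sets, 64 are controls, 13513 pair with exactly 1 gene, 503 pair with several genes and 8730 are not listed in the annotation used here. Probe sets with several genes or none stayed out of the comparisons. Where a gene had several probe sets, the one with the highest mean over the 96 arrays was kept, which left out 157 probe sets and gave 13356 genes. Of these, 13286 matched the TAIR10.1 table, and the others keep the annotation's name. A gene was tested where at least 1 of the 32 groups had a mean of 5 or more (log2), which gave 7281 genes.

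Comparisons were fitted in R 4.3.3 with limma 3.58.1, with 1 mean per group over the 96 arrays (64 residual degrees of freedom), moderated by eBayes. P-values are two-sided and adjusted by Benjamini-Hochberg over the 7281 genes of each comparison. A gene was called at an adjusted p under 0.05 and a change of at least 1 (log2), that is 2-fold. The comparisons were each cell type in standard medium against the mean of the other 3 types, standard 48 h against standard 1 h, and salt at each time against the mean of that cell type's 2 standard groups. They also covered the difference among the 4 salt responses at each time (moderated F test, 3 degrees of freedom) and the change over the 6 salt times in each cell type (moderated F test, 5 degrees of freedom), each with a range of at least 1. The design has no standard group at 3, 8, 20 or 32 h, so salt at those times is compared with standard medium of other durations. The salt comparisons of a cell type share its 6 standard arrays and are not independent of each other.

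Gene lists were tested with camera, which asks whether a list moved relative to other genes, two-sided, with the correlation among members estimated from the data and Benjamini-Hochberg adjustment over all lists and comparisons of a family. Before the data were examined, 32 lists were fixed by gene code, of which 17 had a tested member and 10 had at least 2. Another 27 lists of gene families were compiled from gene codes and symbols after the probe annotation was read and before any comparison was computed, of which 24 had tested members. They were adjusted apart from the fixed lists. Counts of called members are over all genes tested, and for the fixed lists the counts adjusted over the list alone were the same in all but 2 cases, both in the heat shock list.

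Genes named in the text follow a rule fixed before the data were examined. For each cell type and salt time these are the 3 largest rises and 2 largest falls among called genes whose 3 salt arrays all lie beyond all 6 standard arrays. For the difference among cell types these are the 3 genes with the largest range at each time. The rule also takes the 5 largest excesses per cell type, the 2 largest rises and falls between the standard groups, and up to 4 members of each list at the cell type and time with most called members. It further named WER, SCR and WOL, which have no single-gene probe set in the annotation used and are not analysed here.

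Alternatives set beforehand were each standard group alone as reference, quantile normalization, centring each array on its median, and no filter or a stricter filter on dim genes. They also covered eBayes with trend and robust settings, all probe sets in place of 1 per gene, a fit on the 24 arrays of a cell type, the replicate number as a block, a preset inter-gene correlation of 0.01 and leaving out each array in turn. Leaving out the arrays that correlate poorly with their group, and testing the change over time without the 1 h point, were chosen after the data were seen. The code was tested on simulated data of the same size, in which 100 genes were moved by 1.5 (log2) and 100 others by 3. The noise was independent between genes, with the same SD of a gene in all cell types and no shift of scale between arrays. Of the 100 genes moved by 1.5, the code recovered 99 in the salt comparison, with 1 false call among the unmoved of the 7281 genes. In the difference among cell types it recovered 94 of the 100 with 7 false calls. The real arrays differ from these settings, so such rates need not hold for them. In the epidermis, residuals of arrays with the same replicate number correlated at 8 h (0.50, 0.16 and 0.44) and 48 h (0.13, 0.39 and 0.36), as found from the data. At 3 h they did not (0.08, -0.01 and -0.14), so pairing by number is not established. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.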

Results

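Transcript levels were measured on 96 ATH1 arrays of cells sorted from Arabidopsis roots by a GFP reporter for the epidermis, cortex, endodermis or stele. Each cell type has 24 arrays, 3 for each of 8 conditions: standard medium for 1 h and 48 h, and 140 mM NaCl for 1, 3, 8, 20, 32 and 48 h. The series asks how the response to salt unfolds over time and differs between the tissues of the root. Cell type was the main axis of variation, since the first principal component held 36.7% of the variance and 84.8% of that component lay between cell types. Arrays of the same group correlated at 0.916 to 0.997 (median 0.982). Replicates of the cortex were tighter than those of the other types, with a median SD per gene of 0.13 (log2) against 0.25 in the epidermis, 0.22 in the endodermis and 0.23 in the stele. Of all 96 arrays, 3 had a mean correlation under 0.95 with their group, namely epidermis standard 48 h replicate 1 (0.940) and replicate 3 (0.943) and stele standard 1 h replicate 3 (0.933). In what follows, each change is a difference of group means on the log2 scale with its SE, levels are means ± SD, and every salt value rests on 3 salt and 6 standard arrays. The SE and p-value of a gene use a spread pooled over all 96 arrays, not that of the arrays named. They can thus be too small for the epidermis and too large for the cortex.

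To see what each sort held before salt, each cell type in standard medium was compared with the mean of the other 3. Reporter line and sort differ along with the cell type, so the comparison cannot separate them. The epidermis exceeded the others in 440 genes, the cortex in 272, the endodermis in 437 and the stele in 350. In the same order, 815, 45, 350 and 154 genes were lower than in the others. In the epidermis the largest excesses were in AT1G21340, a Dof-type transcription factor, by 3.90 (SE 0.22), AT3G56060 by 3.42 (SE 0.18), the serine carboxypeptidase gene scpl28 by 3.41 (SE 0.20), sks16 by 3.39 (SE 0.24) and AT5G58784 by 3.39 (SE 0.25). In the cortex they were in AT1G09750, an aspartyl protease gene used as a cortex marker, by 2.99 (SE 0.11), AT4G29700 by 2.95 (SE 0.20), the cytochrome P450 gene CYP71B34 by 2.89 (SE 0.12), AT5G57785 by 2.83 (SE 0.22) and AT3G32030, of the terpene synthase family, by 2.77 (SE 0.16). The endodermis stood out in the class III peroxidase gene AT4G36430 by 3.90 (SE 0.19), AT2G22620 (rhamnogalacturonate lyase family) by 3.64 (SE 0.14), AT1G61590 by 3.61 (SE 0.17), AT2G47630 by 3.47 (SE 0.14) and AT5G52790 by 3.47 (SE 0.11). The stele stood out in AT5G24240 by 5.50 (SE 0.11), AT2G21640 by 3.14 (SE 0.16), AT5G09570 by 2.86 (SE 0.15), AT3G28600 by 2.73 (SE 0.21) and AT1G03660 by 2.62 (SE 0.15). The highest adjusted p among these 20 genes was 8.9e-18, each with 6 arrays of its own type against 18.

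Both tested cortex markers were higher in the cortex (mean excess 2.87, camera adjusted p = 0.00673). One of them, AT1G62510, a lipid transfer type protein gene, was at 10.3 ± 0.26 in the cortex, 9.62 ± 0.36 in the endodermis, 8.18 ± 0.46 in the stele and 4.99 ± 0.67 in the epidermis (n = 6 each). GSO1, a receptor kinase gene needed for a continuous Casparian strip, was at 10.3 ± 0.07 in the endodermis and at 4.62 ± 0.55 in the epidermis, an endodermal excess of 3.00 (SE 0.13). The only tested stele marker, LHW, lay between 4.18 ± 0.23 and 4.57 ± 0.23 in the 4 types and was not higher in the stele (excess 0.12, SE 0.11, adjusted p = 0.379). Genes of root hairs, which are epidermal outgrowths, were at least as bright in the stele arrays as in the epidermis arrays. The expansin gene EXPA7 was at 9.16 ± 1.47 in the epidermis, 9.10 ± 0.10 in the cortex, 9.08 ± 0.78 in the endodermis and 9.99 ± 0.40 in the stele, and the stele excess of EXPA18 was 1.37 (SE 0.26, adjusted p = 1.1e-05). WER, SCR and WOL, the genes behind 3 of the reporters, are not analysed here.

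Time on standard medium was examined by comparing 48 h with 1 h. The count was 136 genes in the epidermis (55 higher and 81 lower), 172 in the cortex (86 and 86), 167 in the endodermis (60 and 107) and 457 in the stele (245 and 212). The MADS-box gene AGL42 was higher at 48 h in the cortex by 2.67 (SE 0.37) and in the endodermis by 2.62 (SE 0.37), and AT3G59480 in the cortex by 2.102 (SE 0.34) and in the stele by 2.88 (SE 0.34). AT3G18450 was lower by 48 h, at -2.41 (SE 0.19) in the cortex and -3.14 (SE 0.19) in the stele. The largest rises elsewhere were AT1G50050 (2.75, SE 0.36) and AT2G38240 (2.35, SE 0.29) in the epidermis, AT3G19200 (2.45, SE 0.24) in the endodermis and AT1G19530 (3.43, SE 0.45) in the stele. The largest falls were AT5G40590 (-3.87, SE 0.42) and AT1G52200 (-3.32, SE 0.40) in the endodermis and AT5G48430 (-3.06, SE 0.29) in the stele. The class III peroxidase gene AT1G34510 was lower in the cortex (-2.08, SE 0.59, adjusted p = 0.0119) but not past the threshold without standard 48 h replicate 3 (adjusted p = 0.0541). In the epidermis, AT1G34510 (-2.50, SE 0.59) and the peroxidase gene AT3G49960 (-2.37, SE 0.54) lost their calls when the fit used the 24 epidermis arrays alone (adjusted p = 0.0627 and 0.101). Without epidermis standard 48 h replicate 1 the change was -1.73 (adjusted p = 0.161) for AT1G34510 and -1.07 (adjusted p = 0.357) for AT3G49960. The epidermis count rested on single arrays, falling to 72 without standard 1 h replicate 3 and rising to 385 without standard 48 h replicate 3, and was 58 when only the 24 epidermis arrays were fitted.

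Salt changed 4273 of the 7281 genes in at least 1 cell type and time, 2845 of them in the epidermis, 2511 in the cortex, 2691 in the endodermis and 2497 in the stele. At 1 h the epidermis had 562 called genes, the cortex 737, the endodermis 820 and the stele 902. With 1 array left out these counts ranged from 449 to 787, 729 to 756, 764 to 939 and 785 to 1068, so their order can rest on single arrays. The epidermis reached 1641 genes at 3 h and 2212 at 48 h, the cortex 1814 at 32 h and the endodermis 1776 at 20 h. The stele had 1379 at 3 h, 873 at 20 h and 1621 at 48 h. Falls outnumbered rises at 1 h in the cortex (496 against 241), endodermis (629 against 191) and stele (595 against 307). Responses overlapped between cell types, whose controls are separate arrays. At 48 h the epidermis and cortex shared 598 rising genes where independent lists would share 137, and at 1 h the cortex and stele shared 333 falling genes where 40.5 would be. Even the smallest such overlap at 1 h, of rises in the epidermis and endodermis, held 37 genes against 7.95. In all 4 cell types together, 27 genes were higher and 124 lower at 1 h, and 343 were higher and 328 lower at 48 h.

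**Figure D1:**
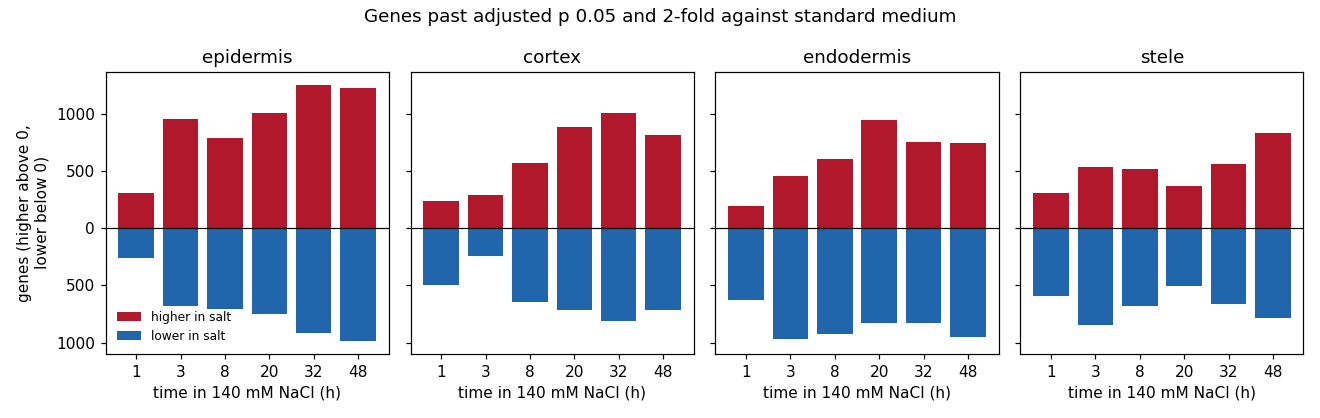
Number of genes called higher (red, above 0) or lower (blue, below 0) in 140 mM NaCl than in standard medium, by cell type (panels) and hours in salt (x axis), each from 3 salt and 6 standard arrays. The epidermis has 1226 genes higher and 986 lower at 48 h, and at 1 h falls outnumber rises in the endodermis (629 against 191), where median centring of the arrays gives 481 falls and 300 rises.

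The scale of the arrays bears on the share of rises. The median change of all tested genes was 0.13, 0.12, 0.14 and 0.16 in the epidermis at 1, 3, 8 and 20 h and 0.14 and 0.13 in the stele at 32 and 48 h. It was within 0.10 in the other 18 comparisons, and a change relative to the median gene is lower by that shift. In the epidermis at 1 h, 53.9% of the calls were rises (303 of 562), against 42.3% (225 rises, 307 falls) after quantile normalization and 34.4% (189 rises, 361 falls) after median centring. At 3 h the share of 58.3% became 48.3% and 42.2%, and under median centring it went from 52.8% to 39.9% at 8 h, from 57.4% to 41.9% at 20 h and from 57.9% to 47.8% at 32 h. In the endodermis the share of rises was 23.3% at 1 h and 31.8% at 3 h, and 38.4% and 42.0% under median centring. Signs of RNA quality, the differences between the 3′ and 5′ probe sets of 3 control transcripts, moved with some groups. In the endodermis at 1 h of salt the GAPDH difference was 1.43 ± 0.07 against 0.48 ± 0.15 in its standard arrays and the ubiquitin difference 1.17 ± 0.02 against 1.01 ± 0.08, each with all 3 salt arrays above all 6 standard arrays. The actin difference overlapped there (3.44 ± 0.08 against 3.48 ± 0.15). GAPDH also lay above all standard arrays in the endodermis at 3 h (0.85 ± 0.04), 8 h (0.89 ± 0.21) and 48 h (0.71 ± 0.10) and in the cortex at 3 h (0.62 ± 0.06 against 0.36 ± 0.09). So did ubiquitin in the endodermis at 20 h (1.19 ± 0.05) and 48 h (1.24 ± 0.05). Actin did so in the cortex at 32 h (4.22 ± 0.22) and 48 h (3.96 ± 0.10), against 3.63 ± 0.19, and in the epidermis at 48 h (3.93 ± 0.09 against 3.41 ± 0.26). Of 72 such comparisons, 11 lay above and 1 below, the ubiquitin difference in the epidermis at 1 h (1.11 ± 0.01 against 1.27 ± 0.10), where exchangeable arrays would give 1.71. Means also shifted where arrays overlapped. In the stele the GAPDH difference at 1 h was 0.95 ± 0.46 against 0.46 ± 0.20, and the actin difference at 48 h was 3.93 ± 0.20 against 3.43 ± 0.32.

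In the epidermis at 1 h, LEA4-5, a late embryogenesis abundant (LEA) gene, rose by 3.44 (SE 0.25), from 7.65 ± 0.98 to 11.1 ± 0.50. The dehydrin gene AT4G38410 rose by 3.47 (SE 0.21) at 1 h and was higher by 4.04 (SE 0.21) at 3 h, 4.21 (SE 0.21) at 8 h and 3.96 (SE 0.21) at 32 h. AT3G51750 rose by 3.58 (SE 0.28) at 1 h, and AT1G52680 by 4.37 (SE 0.24) and AT5G66780 by 4.18 (SE 0.33) at 3 h. Later rises were led by AT4G27450 at 20 h (5.04, SE 0.36, though with an SD of 1.62 among its 3 salt arrays). Others were the rhodanese-type gene AT2G17850 at 8 h (3.77, SE 0.28) and 20 h (4.41, SE 0.28), the CTP synthase gene AT1G30820 at 8 h (3.52, SE 0.21), 20 h (4.01, SE 0.21) and 48 h (4.18, SE 0.21). With them came the bHLH gene AT2G22760 at 32 h (4.07, SE 0.40) and 48 h (3.84, SE 0.40), and JRG21, a dioxygenase gene known for its response to jasmonate, at 32 h (4.57, SE 0.35) and 48 h (4.56, SE 0.35). AT3G21340, a leucine-rich repeat receptor kinase gene, dropped by 4.27 (SE 0.23) at 3 h and 5.64 (SE 0.23) at 48 h, from 8.05 ± 0.44 to 2.40 ± 0.23. The wall loosening gene EXPB1 was lower at 20 h (-4.28, SE 0.28) and 32 h (-5.01, SE 0.28), the glyoxal oxidase related AT1G19900 at 48 h (-5.05, SE 0.27), AT5G43520 at 8 h (-4.61, SE 0.29), AT1G78260 at 3 h (-4.18, SE 0.23), and the lipase family gene AT2G40250 (-3.04, SE 0.22) and AT3G46280 (-3.00, SE 0.28) at 1 h. The highest adjusted p in this paragraph was 1.5e-13.

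In the cortex at 1 h, AT3G17520, a LEA gene, rose by 4.48 (SE 0.29), AT5G66780 by 4.80 (SE 0.33) and AT3G51750 by 4.33 (SE 0.28), while AT3G46280 (-4.33, SE 0.28) and the xyloglucan endotransglucosylase gene XTH21 (-3.62, SE 0.22) fell. At 3 h the peroxidase genes AT4G36430 (3.92, SE 0.28) and PRX52 (AT5G05340, 3.86, SE 0.28) were among the largest rises, and AT5G66780 stayed higher by 3.92 (SE 0.33). The subtilase gene ATSBT5.2 (-2.82, SE 0.31) and AT4G39675 (-2.72, SE 0.40) were the largest falls. At 8 h AT5G12420, of the wax ester synthase and diacylglycerol acyltransferase family, rose by 5.09 (SE 0.32), AT4G38080 by 4.91 (SE 0.36) and PRX52 by 4.69 (SE 0.28). AT3G32030 fell by 4.25 (SE 0.23) together with AT3G21340 (-4.21, SE 0.23). Before salt AT3G32030 was at 9.11 in the cortex, 8.27 in the endodermis, 7.07 in the stele and 3.67 in the epidermis. At 20 h the largest rises were AT1G26380, of the berberine bridge enzyme family (5.22, SE 0.41), JRG21 (4.58, SE 0.35) and the beta-glucosidase gene BGLU27 (4.23, SE 0.26). AT4G01140 was lower (-3.91, SE 0.24). At 32 h they were JRG21 (4.21, SE 0.35), the thaumatin family gene AT1G73620 (3.87, SE 0.35) and the methyltransferase family gene AT5G38020 (3.69, SE 0.20). The pectin lyase family gene AT2G43890 was lower (-4.02, SE 0.33). At 48 h AT1G14120, an oxoglutarate-dependent dioxygenase family gene, went from 2.73 ± 0.09 to 8.04 ± 0.11, a rise of 5.31 (SE 0.14, adjusted p = 4.3e-44). There AT5G38020 rose by 5.21 (SE 0.20) and the jacalin lectin gene JAL22 by 4.49 (SE 0.20), and XTH21 was lower (-3.37, SE 0.22). AT3G21340 was also lower at 20 h (-4.22, SE 0.23), 32 h (-4.32, SE 0.23) and 48 h (-4.17, SE 0.23). The highest adjusted p among the cortex genes was 1.1e-07, for AT4G39675.

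In the endodermis, the peroxidase gene AT1G68850 went from 3.08 ± 0.14 to 10.1 ± 0.41 at 8 h, a rise of 7.01 (SE 0.26), and was still higher by 5.60 (SE 0.26) at 20 h. AT4G38080 rose by 6.87 (SE 0.36) at 3 h, 6.90 (SE 0.36) at 8 h and 6.30 (SE 0.36) at 20 h. The GDSL lipase gene AT3G50400 rose by 4.43 (SE 0.31) at 1 h, 6.81 (SE 0.31) at 3 h and 6.51 (SE 0.31) at 8 h, the GDSL lipase gene AT2G23540 by 5.22 (SE 0.22) at 20 h, and PRX52 by 6.21 (SE 0.28) at 3 h. At 1 h AT3G17520 rose by 4.73 (SE 0.29) and AT4G12580 by 4.66 (SE 0.23). There AT3G46280 (-4.40, SE 0.28) and XTH21 (-4.09, SE 0.22) fell. At 3 h the glutathione transferase gene GSTU28 (-4.66, SE 0.36) and AT3G45700 (-4.60, SE 0.26) were the largest falls. The cortex marker AT1G62510 dropped by 5.92 (SE 0.35) at 8 h, from 9.62 ± 0.36 to 3.69 ± 0.32, and by 4.78 (SE 0.35) at 20 h. EXPB1 was lower at 8 h (-4.82, SE 0.28) and 32 h (-4.37, SE 0.28), and AT3G21340 at 20 h (-4.52, SE 0.23). From 32 h the leading rises were JRG21 (4.80, SE 0.35), AT4G38410 (4.44, SE 0.21 at 32 h and 4.64, SE 0.21 at 48 h), AT3G54150 (4.13, SE 0.28 at 32 h and 4.67, SE 0.28 at 48 h) and, at 48 h, the alkenal reductase gene AER (4.65, SE 0.28). AT2G43890 was lower at 32 h (-4.69, SE 0.33), and tny, an AP2/ERF transcription factor gene, and EXPA7 were lower at 48 h (-4.86, SE 0.25 and -4.65, SE 0.39). The highest adjusted p among the endodermis genes was 1.4e-16.

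In the stele, PRX52 rose by 5.64 (SE 0.28) at 3 h and 7.57 (SE 0.28) at 8 h, from 2.84 ± 0.21 to 10.4 ± 0.27, and was higher by 4.13 (SE 0.28) at 20 h and 4.37 (SE 0.28) at 48 h. The osmotin gene OSM34, of the thaumatin-like defence proteins, rose late, by 4.05 (SE 0.30) at 32 h and 4.43 (SE 0.30) at 48 h. The lipid transfer type gene AT1G73780 rose by 3.70 (SE 0.22) at 20 h, 4.07 (SE 0.22) at 32 h and 3.76 (SE 0.22) at 48 h, and AT2G37870, of the same kind, by 3.63 (SE 0.28) at 32 h. At 1 h the largest rises were AT3G17520 (4.75, SE 0.29), AT1G04560 (4.01, SE 0.22) and AT4G12580 (3.71, SE 0.23). At 3 h they were AT5G12420 (5.48, SE 0.32) and AT3G50400 (4.93, SE 0.31), at 8 h AT1G65500 (5.41, SE 0.29) and AT3G50400 (4.88, SE 0.31), and at 20 h AT2G17850 (3.74, SE 0.28). Falls were led by AT1G19900 (-4.09, SE 0.27) and AT5G45480 (-4.05, SE 0.19) at 1 h, by the lipid transfer type genes AT1G62510 (-4.30, SE 0.35) and AT2G45180 (-4.15, SE 0.22) at 3 h. At 8 h they were led by AT3G21340 (-5.23, SE 0.23) and AT1G62510 (-4.95, SE 0.35). At 20 h they were AT1G66460 (-3.92, SE 0.21) and AT3G21340 (-3.87, SE 0.23), and later AT3G21340 at 32 h (-5.04, SE 0.23) and 48 h (-5.34, SE 0.23), AT2G43890 at 32 h (-3.61, SE 0.33) and AT1G19900 at 48 h (-4.18, SE 0.27). The highest adjusted p among the stele genes was 3.4e-15.

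Many of these changes start or end in the lower part of the scale. In the standard arrays concerned, AT1G14120 in the cortex lay above 14.7% of the probe sets, PRX52 in the stele above 18.01% and in the cortex above 12.7%, and AT1G68850 and AT4G38080 in the endodermis above 24.8% and 29.7%. AT3G21340 in the epidermis at 48 h of salt lay above 5.55%. No background level was established for these arrays, so the sizes of such changes are uncertain. Among others, this applies to AT4G12580, AT3G50400 and AT1G73780 in the stele, which were at 2.79, 3.04 and 2.94 in standard medium.

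**Figure D2:**
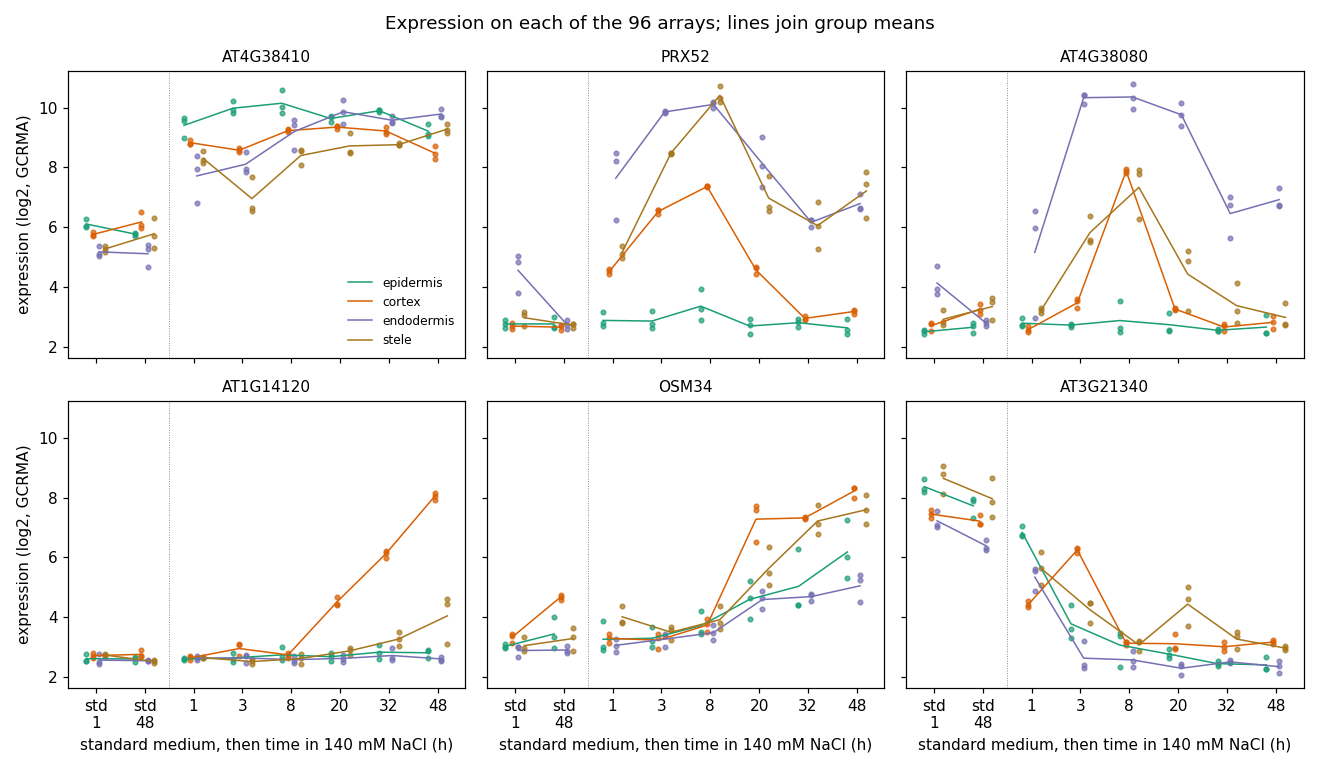
Log2 expression (y axis) of 6 named genes on each of the 96 arrays, with standard medium for 1 and 48 h at the left and hours in 140 mM NaCl to the right, colours for cell types and lines joining means of 3 arrays. PRX52 peaks at 8 h in the stele (10.4) and stays near 3 in the epidermis, while AT1G14120 reaches 8.04 in the cortex at 48 h.

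Among gene groups, the LEA family of dehydration proteins stood out early. Of its 20 tested members, 10 rose and 0 fell in the cortex at 1 h (mean change 1.30, camera adjusted p = 0.00387), with AT3G17520 up by 4.48, AT3G15670 by 3.27 (SE 0.31), AT4G38410 by 2.86 (SE 0.21) and AT3G02480 by 2.59 (SE 0.23). At 1 h 6 members rose in the epidermis, 4 in the endodermis and 8 in the stele, with 1 falling in the stele, and the list was not called there (adjusted p = 0.229, 0.229 and 0.069). The GAPDH difference at that time was 1.43 in the endodermis and, overlapping its standard arrays, 0.95 in the stele. Of the fixed list of 31 genes for abscisic acid and dehydration, 4 were measured. In the cortex at 1 h COR15B rose by 2.03 (SE 0.12) and COR15A by 1.81 (SE 0.11), the list's mean was 1.15 (camera adjusted p = 0.0365), and LTI30 and COR47, already near 13, changed by 0.45 and 0.32. Both list calls were lost under median centring, although the array medians shifted by only 0.03 in this comparison. Under median centring the adjusted p was 0.174 for the LEA family and 0.224 for the dehydration list, which also missed the threshold under quantile normalization (0.184) and against standard 48 h alone (0.138). The 2 tested small heat shock protein genes rose in the cortex at 20 h, ATHSP22.0 by 3.32 (SE 0.47) and AT1G53540 by 2.81 (SE 0.59), as both did in the endodermis at 20 h, where the ubiquitin control was at 1.19 against 1.01, and both fell in the stele at 3 h (list adjusted p = 0.821, 0.821 and 0.827). Adjusted over the list alone, the heat shock counts differed only in the epidermis at 20 h (0 in place of 1 gene) and in the cortex at 1 h (2 in place of 1). The only measured proline gene, AT5G38710, which encodes a proline dehydrogenase that degrades proline, rose in the cortex at 48 h by 2.11 (SE 0.27).

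Genes of cytosolic ribosomal proteins rose in all 4 cell types. Of 102 tested members, 83 rose in the epidermis at 3 h and 101 at 32 h, 102 in the cortex at 32 h, 79 in the endodermis at 20 h and 100 in the stele at 48 h, and 0 fell at any time in any cell type. The mean change was 1.92 in the cortex at 32 h, and relative to the median gene it was 1.14 in the epidermis at 3 h, 1.67 in the epidermis at 32 h and 1.38 in the stele at 48 h. AT4G30800 (3.09, SE 0.30), AT1G23410 (2.75, SE 0.34), AT1G80750 (2.55, SE 0.23) and AT4G10450 (2.54, SE 0.30) rose most in the cortex at 32 h. The actin control difference was 4.22 there against 3.63 in standard arrays, and in the endodermis at 20 h the ubiquitin control was at 1.19 against 1.01. In the endodermis at 1 h, where the GAPDH and ubiquitin controls shifted, 0 members were called and the mean was -0.19. Members vary together, and with an estimated correlation the list was not called at any of 24 comparisons (adjusted p 0.398 in the cortex at 32 h). Median centring lowers the count in the epidermis from 83 to 56 at 3 h and from 74 to 46 at 8 h. The 3 members on the fixed ribosomal list, AT2G19730, AT3G09630 and AT5G02870, rose by 1.79 (SE 0.19), 1.77 (SE 0.19) and 1.66 (SE 0.21) in the cortex at 32 h (list adjusted p = 0.821). In the cortex at 32 h, beside the same actin shift, 7 of 7 genes of the G2 and M phases were higher (mean 1.76, adjusted p = 0.451), among them 3xHMG-box2 (2.28, SE 0.33), TOPII (2.27, SE 0.30), 3xHMG-box1 (2.12, SE 0.23) and AT4G15830 (1.72, SE 0.25). The kinase genes AUR2 (1.20, SE 0.25) and AUR1 (1.11, SE 0.22) were past 2-fold too (list adjusted p = 0.821), but against standard 48 h alone they were at 0.94 and 0.99. In the epidermis, the replication gene PRL rose by 1.99 (SE 0.24) at 32 h, and 4 of 8 histone genes rose at 48 h, HTB2 by 1.35 (SE 0.26), HTB4 by 1.24 (SE 0.13), AT5G02570 by 1.14 (SE 0.15) and HTB1 by 1.13 (SE 0.16), with an adjusted p of 0.549 for the list and an actin control difference of 3.93 against 3.41.

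Of 7 extensins, structural wall proteins, 7 fell in the epidermis at 32 h (mean -2.20, adjusted p = 0.404), with AT3G28550 at -3.11 (SE 0.39), AT1G23720 at -2.68 (SE 0.30), HRGP1 at -2.24 (SE 0.30) and AT4G08410 at -2.08 (SE 0.31). In the endodermis 6 fell at 48 h, in the stele 6 and in the cortex 4. At 48 h the GAPDH control was at 0.71 in the endodermis and the actin control at 3.96 in the cortex and 3.93 in the epidermis, above their standard arrays. The 3 root hair genes fell in the epidermis at 48 h, EXPA7 by 3.35 (SE 0.39), EXPA18 by 2.62 (SE 0.40) and XTH26 by 1.87 (SE 0.32), and in the stele at 3 h (list adjusted p = 0.821 in both), although against standard 48 h alone XTH26 was at -0.73 (adjusted p = 0.0788). Expansins and xyloglucan transferases went both ways. Of the 7 on the fixed list, 5 fell in the endodermis at 1 h (adjusted p = 0.136), beside the GAPDH and ubiquitin shifts at that time. In the stele at 3 h EXPB1 (-3.48, SE 0.28) and XTH21 (-1.71, SE 0.22) fell while XTH20 (2.44, SE 0.31) and EXPA4 (2.02, SE 0.21) rose (2 up and 4 down in all, adjusted p = 0.821). In the whole families there, 6 of 12 expansins fell and 2 rose, with EXPA8 at -1.90 (SE 0.32) and EXPA18 at -1.82 (SE 0.40), and 6 of 8 XTH genes fell and 1 rose, with XTH26 at -2.85 (SE 0.32) and XTH33 at -2.23 (SE 0.23) (adjusted p = 0.524 and 0.269). COB, needed for oriented cellulose deposition, fell in the endodermis at 8 h by 1.21 (SE 0.16). At 3 h in the endodermis 4 of 7 tubulin genes fell, TUB1 at -2.23 (SE 0.24), TUB5 at -1.86 (SE 0.20), TUB7 at -1.68 (SE 0.17) and TUA6 at -1.60 (SE 0.16). So did 8 of 16 TBL genes of wall acetylation, led by TBL21 at -2.76 (SE 0.35), TBL28 at -1.82 (SE 0.19), TBL34 at -1.79 (SE 0.27) and TBL38 at -1.72 (SE 0.20), with an adjusted p of 0.359 for each list. The GAPDH difference in the endodermis at 3 h was 0.85 against 0.48 in standard arrays. GSO1 of the Casparian strip fell in the cortex at 20 h by 1.89 (SE 0.20), its largest called change over the 24 salt comparisons.

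Class III peroxidases, enzymes of wall cross-linking, moved in both directions. In the endodermis at 8 h, 13 of 40 rose and 13 fell, with AT1G68850 up by 7.01, PRX52 by 6.46 (SE 0.28), AT4G08780 by 4.74 (SE 0.25) and AT1G14550 by 4.47 (SE 0.34). The GAPDH control was at 0.89 in the endodermis at 8 h, against 0.48. The epidermis had 1 rise and 18 falls at 8 h (list adjusted p = 0.229). Of 11 beta-glucosidases 6 rose in the stele at 3 h, with BGLU28 up by 3.34 (SE 0.30), BGLU24 by 2.93 (SE 0.23), BGLU45 by 2.82 (SE 0.24) and BGLU27 by 2.15 (SE 0.26) (list adjusted p = 0.133). In addition, 4 rose in the cortex at 20 h (adjusted p = 0.0603). Of 21 AP2/ERF transcription factor genes, 12 fell and 1 rose in the endodermis at 3 h (adjusted p = 0.366), with tny at -3.67 (SE 0.25), ORA47 at -2.79 (SE 0.31), AT5G61590 at -2.38 (SE 0.27) and AT1G44830 at -1.94 (SE 0.27). The GAPDH control was at 0.85 there. Among 6 auxin response genes, WES1 (-2.42, SE 0.27), LBD29 (-2.40, SE 0.21) and IAA29 (-1.85, SE 0.22) fell in the endodermis at 20 h and GH3.1 was at 0.77 (list adjusted p = 0.821), with the ubiquitin control at 1.19 against 1.01. The gibberellin receptor gene GID1A rose in the epidermis at 3 h by 1.09 (SE 0.15), but by 0.90 under median centring and 0.85 under quantile normalization, and GID1B and GID1C were at 0.23 and -0.12 (list adjusted p = 0.895). WRKY53 rose in the cortex at 8 h by 1.64 (SE 0.30) with STZ at 0.59 (list adjusted p = 0.821), and the calmodulin-like gene CML38 in the endodermis at 8 h by 1.58 (SE 0.21). Both cortex markers fell in the endodermis at 8 h (mean -4.14, adjusted p = 0.275), AT1G09750 by 2.35 (SE 0.16), beside the GAPDH shift of that group, and LHW rose there at 20 h by 1.46 (SE 0.17). The single antioxidant gene with a tested probe set was called at no time in any cell type. The fixed lists for abscisic acid receptors, jasmonate, ethylene, auxin transport, brassinosteroid, cytokinin, ion transport, aquaporins, secondary wall, suberin, nitrate, iron and the markers of epidermis, endodermis and root cap had no tested member and are not analysed here.

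**Figure D3:**
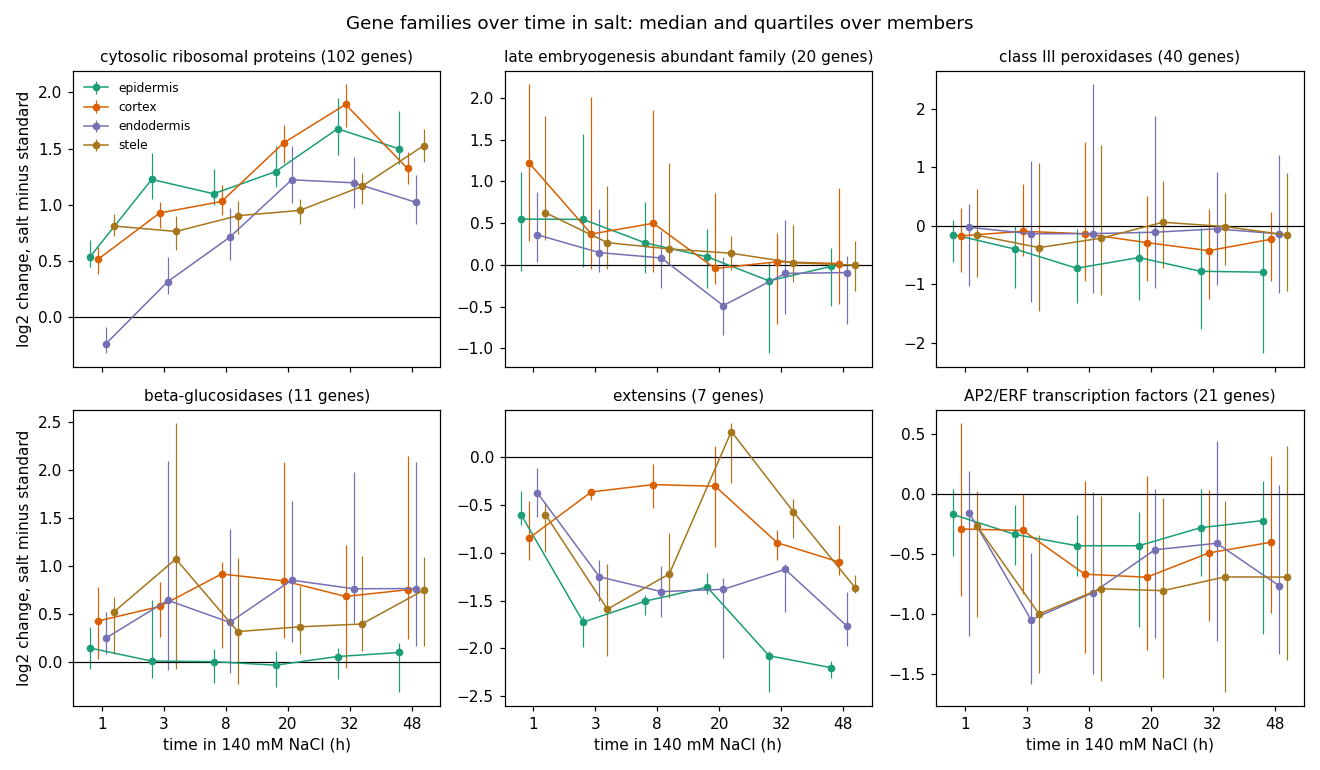
Median log2 change of 6 gene families (y axis) in 140 mM NaCl relative to standard medium against hours in salt (x axis), by cell type, with bars from the lower to the upper quartile over the members. The median of the ribosomal protein genes is highest in the cortex at 32 h (1.89) and lower there at 48 h (1.32), with the list called at none of 24 comparisons, and beta-glucosidases stay near 0 in the epidermis, where the sign at 3 h turns under median centring.

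Whether the response depends on the cell type was tested directly, gene by gene, at each time. It differed in 1555 genes at 1 h, 2514 at 3 h, 2043 at 8 h, 2223 at 20 h, 2141 at 32 h and 1954 at 48 h, which is 21.4% to 34.5% of those tested. Each cell type has its own reporter line and sorts, so the test cannot tell a difference between lines or sorts from one between cell types. At 3 h the response of AT4G38080 was 6.87 in the endodermis, 2.69 in the stele, 0.49 in the cortex and 0.15 in the epidermis (adjusted p = 7.5e-19). AT1G05450 rose by 5.99 in the endodermis at 3 h against -0.30 in the epidermis (adjusted p = 1.1e-16). At 8 h PRX52 rose by 7.57 in the stele, 6.46 in the endodermis and 4.69 in the cortex against 0.59 in the epidermis (adjusted p = 6.2e-24). AT5G19875 went from 3.13 in the epidermis to -1.21 in the endodermis at 1 h (adjusted p = 1.2e-13). The heat shock gene AT1G53540 rose by 2.90 in the endodermis at 20 h and fell by 2.62 in the stele (adjusted p = 6.6e-08). AT5G51440, of a mitochondrial heat shock protein, was at -3.24 in the epidermis and 0.91 in the endodermis at 32 h (adjusted p = 3.9e-08). At 32 h the peroxidase gene AT4G16270 was at 2.50 in the endodermis and -1.70 in the cortex (adjusted p = 3.0e-14), and AT1G73780 at 4.07 in the stele and -0.06 in the cortex (adjusted p = 2.0e-19). At 48 h AT1G14120 was at 5.31 in the cortex and 0.05 in the endodermis (adjusted p = 6.1e-36). Genes called in opposite directions in different cell types numbered 22, 47, 68, 61, 39 and 45 from 1 to 48 h. Among the gene lists, the class III peroxidases responded lower in the epidermis than in the other types from 3 h on, with camera adjusted p values of 0.0111 at 3 h, 0.000824 at 8 h (-1.12 on average), 0.00727 at 20 h, 0.0268 at 32 h and 0.0269 at 48 h. The calls at 3, 32 and 48 h were lost under both other scalings (adjusted p 0.0523 to 0.101). The beta-glucosidases also responded lower in the epidermis, by -1.09 at 48 h (adjusted p = 0.000268), where the actin control was at 3.93 in the epidermis against 3.41. Control transcripts also stood apart in endodermis and cortex groups that the epidermis was compared with. At 1 h the cortex was above the other types in the dehydration list by 0.77 (adjusted p = 0.0033) and in the LEA family by 0.49 (adjusted p = 0.0211), and neither passed under median centring (adjusted p = 0.0998 and 0.221).

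Change over the 6 salt times, which uses no standard array, was found in 1945 genes in the epidermis, 1931 in the cortex, 2209 in the endodermis and 1591 in the stele. A change with age or time on the medium is therefore counted along with a change due to salt. On standard medium alone, 136 (epidermis) to 457 (stele) genes differed between 1 h and 48 h. Genes differed in when they moved, as the plot of single arrays shows. PRX52 in the cortex went from 2.67 ± 0.08 in standard medium to 7.36 ± 0.02 at 8 h and was at 0.50 above standard at 48 h, which was not a call. JRG21, which is not in that plot, was at 9.52 ± 0.02 in the cortex at 20 h and 9.14 ± 0.13 at 32 h. Without the 1 h point, chosen for leaving out after the data were seen, the counts were 823 in the epidermis, 1040 in the cortex, 1244 in the endodermis and 1330 in the stele, with 5 times compared in place of 6.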

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

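The tests of differences among cell types were set before the data were examined. The membership of the added gene families and the count of probe sets without a single gene came after the probe annotation was read. The response to salt differed between cell types, by the F test of the difference itself, in 1555 genes at 1 h, 2514 at 3 h, 2043 at 8 h, 2223 at 20 h, 2141 at 32 h and 1954 at 48 h. Reporter line and sort differ along with the cell type and cannot be separated from it here.

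The 3 genes with the widest fitted range among the 4 responses at each time make 13 genes in all, 4 of them named at more than 1 time. AT4G12580 spanned 4.53, AT5G19875 4.34 and AT3G50400 4.24 at 1 h (log2 throughout). AT4G38080 spanned 6.73, AT3G50400 6.47 and AT1G05450 6.29 at 3 h. PRX52 spanned 6.98, AT1G68850 6.91 and AT4G38080 6.60 at 8 h, and at 20 h AT4G38080 spanned 6.14, AT1G68850 5.76 and the heat shock gene AT1G53540 5.52. AT4G16270 spanned 4.20, AT5G51440 4.16 and AT1G73780 4.13 at 32 h, and AT1G14120 5.26, AT5G38020 5.01 and PRX52 4.502 at 48 h. In PRX52, AT1G68850, AT4G38080, AT3G50400, AT1G05450 and AT4G12580 the epidermis had the lowest response at each time named here. The highest was in the endodermis for these genes, apart from PRX52, where it was in the stele. AT5G19875 was highest in the epidermis, AT1G73780 in the stele and AT1G14120 and AT5G38020 in the cortex. The ranges of PRX52, AT4G38080, AT1G68850, AT1G14120, AT3G50400, AT4G12580, AT1G05450 and AT1G73780, among others, involve levels in the lower part of the scale, so their sizes and order are uncertain.

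The class III peroxidases responded lower in the epidermis than the mean of the other cell types, by -0.76 at 3 h, -1.12 at 8 h, -0.78 at 20 h, -0.79 at 32 h and -0.75 at 48 h. The beta-glucosidases did so as well, by -0.80, -0.97, -1.02, -0.93 and -1.09 at the same times. They were above the mean of the other types in the cortex at 20 h (0.83) and in the endodermis at 32 h (0.72) and 48 h (0.68). Control transcripts stood apart in some of the groups compared. The GAPDH difference was 0.85 at 3 h and 0.89 at 8 h in the endodermis, against 0.48, and 0.62 at 3 h in the cortex, against 0.36. The ubiquitin difference of the endodermis was 1.19 at 20 h, against 1.01, and the actin difference of the cortex 4.22 at 32 h and 3.96 at 48 h, against 3.63. At 48 h the GAPDH (0.71 against 0.48) and ubiquitin (1.24 against 1.01) controls of the endodermis and the actin control of the epidermis (3.93 against 3.41) lay above all standard arrays of their type. In the cortex at 1 h the dehydration list was above the other types by 0.77 and the LEA family by 0.49, while GAPDH (1.43 against 0.48) and ubiquitin (1.17 against 1.01) stood apart in the endodermis and ubiquitin in the epidermis (1.11 against 1.27). Among these list differences, those of the peroxidases at 3, 32 and 48 h, of the beta-glucosidases in the epidermis at 3 h and in the endodermis, and of both lists in the cortex at 1 h missed the threshold under at least 1 other scaling.

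Probe sets with no gene or several genes in the annotation used here were left out of every comparison above. Run through the same salt comparisons, 3941 of 6346 such probe sets were called in at least 1 cell type and time, so a large part of the salt response on this array is not described by the named genes.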

How the results depend on the processing

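The alternatives without the poorly correlating arrays and without the 1 h salt point were chosen after seeing the data, and the others beforehand. Apart from leave-one-out runs, 390 of 438 recomputed gene counts stayed within 1.5 times their value. Of the recomputed values of named genes, 2746 kept direction and side of the threshold, 26 lost their call, 2 gained one and 2 changed sign or went to 0. With all probe sets in place of 1 per gene more features are tested, which raises every count. Salt calls from 1 to 48 h became 1050, 3027, 2813, 3254, 4034 and 4108 in the epidermis, 1476, 1034, 2343, 3007, 3389 and 2812 in the cortex, 1634, 2812, 2979, 3429, 3019 and 3251 in the endodermis and 1693, 2707, 2345, 1651, 2274 and 3034 in the stele. In the order epidermis, cortex, endodermis, stele, the cell type excesses became 773, 594, 891 and 709, the standard 48 h against 1 h counts 258, 364, 323 and 864, and the changes over time 3727, 3835, 4339 and 3265. The differences among cell types became 3060, 4911, 4068, 4314, 4054 and 3817. A stricter filter left fewer genes and gave 84 (epidermis) and 299 (stele) between the standard groups, and the 24 epidermis arrays alone gave 58. Change over time without the 1 h point gave 823, 1040 and 1244 in the epidermis, cortex and endodermis. Leaving out 1 array at a time, where the remaining arrays of a group are assumed to vary like the others, moved 3 of 624 counts by over 1.5 times, all between the epidermis standard groups (72 to 385). The number of gene lists called in salt, 1 of the fixed and 1 of the added, is the result that depends most on the settings. It was 9 and 108 with a preset correlation, 2 and 5 against standard 1 h alone, 0 fixed against standard 48 h alone, 0 and 5 after quantile normalization, 0 and 0 after median centring and 5 and 5 with no filter. With the replicate number as a block it was 0 for the fixed lists, the dehydration list in the cortex at 1 h having an adjusted p of 0.0558, and the difference of the beta-glucosidases in the endodermis at 48 h had 0.0563. Counts of genes say little about the block, which leaves the changes themselves as they are. The residuals of arrays with the same number correlated at a median of -0.01 over 72 pairs, with 17 over 0.1, of which 9 of 18 are in the epidermis. Outside the epidermis at 8 and 48 h, no comparison of salt with standard had all 3 pairs over 0.1, so no pairing was found there. The correlations in the epidermis at 8 and 48 h were not tested against other matchings of the arrays. List differences among cell types, 1 fixed and 14 added, became 2 and 95 with a preset correlation, 0 fixed after quantile normalization and 0 and 7 after median centring. A few values changed sign or reached 0. In the epidermis at 3 h GID1C went to 0.0066 without standard 1 h replicate 2 and to 0.157 without standard 48 h replicate 1, and without replicate 3 of that group it was -0.365. In the cortex at 1 h COR47 became 0 after quantile normalization. In the stele at 1 h SWEET11 became -0.0655 against standard 48 h alone. With no filter the AGAMOUS-like list in the epidermis at 32 h became -0.0215 and the subtilases in the endodermis at 3 h -0.0341. Unless named, the cause was not tested. Signal near background limits dim genes, and 7281 of 13356 genes passed the filter.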

Other observations

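Among the tests in this part, the one for free RNA and the one for RNA degradation were chosen only after the result was seen. The rule for reading the degradation test was also revised after its values were seen, because the control transcripts disagreed. Members of several further gene families were called, while no list of these families was called in salt. In the stele at 1 h 4 of 8 SWEET sugar transporter genes rose and 0 fell, SWEET4 by 2.16 (SE 0.13), SWEET14 by 1.59 (SE 0.21), SWEET11 by 1.15 (SE 0.38) and SWEET1 by 1.02 (SE 0.17), with a list adjusted p of 0.611. SWEET11 was at -0.0655 against standard 48 h alone, and SWEET1 at 0.82 against standard 1 h alone. The GAPDH control difference in the stele at 1 h was 0.95 ± 0.46 against 0.46 ± 0.20 in standard arrays, with overlap. In the endodermis at 8 h 4 of 7 tau glutathione transferase genes fell and 1 rose, GSTU28 by -4.26 (SE 0.36), GSTU26 by -1.79 (SE 0.18), GSTU27 by -1.43 (SE 0.21) and GSTU22 by -1.14 (SE 0.14), with a list adjusted p of 0.366. The GAPDH control difference was 0.89 there against 0.48 in standard arrays. Of 8 tetraspanins 5 fell and 1 rose there, TET5 at -1.996 (SE 0.37), TET6 at -1.93 (SE 0.24), TET2 at -1.88 (SE 0.20) and TET12 at -1.78 (SE 0.34) (adjusted p = 0.412). In the endodermis at 48 h, where the GAPDH control was at 0.71 and the ubiquitin control at 1.24 against 1.01, 8 of 33 UDP-glycosyltransferase genes rose and 8 fell (adjusted p = 0.941). UGT76E12 changed by 3.77 (SE 0.22), UGT71C1 by -3.34 (SE 0.31). UGT72E3 and UGT72E2, which act on monolignols, were at -3.06 (SE 0.18) and -2.60 (SE 0.15). Of 12 cytochrome P450 genes 2 rose and 5 fell there, CYP718 at -2.68 (SE 0.23), CYP71B6 at 1.84 (SE 0.15), CYP71B34 at -1.37 (SE 0.17) and CYP78A9 at -1.10 (SE 0.20) (adjusted p = 0.682).

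Signalling and protein handling genes changed one by one and no list of them was called. In the stele at 48 h the RALF-like peptide genes split, RALFL27 at -2.92 (SE 0.25), RALFL34 at 1.54 (SE 0.20), RALFL31 at 1.16 (SE 0.17) and RALFL22 at -1.07 (SE 0.15), with 2 up and 2 down of 7 (adjusted p = 0.854). At 32 h there 3 of 6 calmodulin-like genes fell and 1 rose, CML37 at -1.83 (SE 0.19), CML43 at -1.38 (SE 0.18), CML30 at 1.34 (SE 0.29) and CML23 at -1.19 (SE 0.19) (adjusted p = 0.524). Of 13 serine carboxypeptidase-like genes 4 fell and 1 rose in the epidermis at 48 h, where the actin control was at 3.93 against 3.41, scpl40 at -2.02 (SE 0.27), scpl28 at -1.67 (SE 0.31), SCPL34 at -1.27 (SE 0.20) and scpl50 at 1.101 (SE 0.15) (adjusted p = 0.791). Of 16 secretion and vacuolar sorting genes 1 rose and 2 fell there, VPS2.2 at 1.82 (SE 0.29), SEC15B at -1.17 (SE 0.12) and SEC6 at -1.09 (SE 0.15), with SEC1B at -0.79 (adjusted p = 0.802). Of 5 AGAMOUS-like genes 2 rose and 1 fell in the epidermis at 32 h, AGL16 at -1.21 (SE 0.17), AGL26 at 1.15 (SE 0.11) and AGL18 at 1.11 (SE 0.19), with AGL21 at 0.91 (adjusted p = 0.700). In the endodermis the subtilase genes SBT4.12 (-2.28, SE 0.34), SBT3.5 (1.25, SE 0.18) and SBT3.3 (1.16, SE 0.21) changed at 3 h (adjusted p = 0.775), with the GAPDH control at 0.85. Of 19 ubiquitin pathway genes 3 rose and 1 fell there at 32 h, UBC20 at 2.20 (SE 0.27), UBC37 at 1.23 (SE 0.17), PUB19 at -1.16 (SE 0.18) and PUB24 at 1.13 (SE 0.24) (adjusted p = 0.768).

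The rise of cytosolic ribosomal protein genes is not explained by a normalization that lifts all bright genes, since their median lay above lists of equally bright genes in 23 of 24 comparisons, the exception being the endodermis at 1 h (-0.24, matched lists -0.19 to 0.06). For scaling between arrays only the cortex at 32 h was tested, where 102 of the 102 genes were called higher under the lower of 2 other scalings. The array medians shifted there by much less than these genes rose, so median centring could not have removed the calls. A shift of the medians is thus too small to give the rise in that comparison, but the test does not decide on scaling in the others. In the epidermis at 3 and 8 h median centring lowered the counts, so scaling as part of the cause stays open there. An age difference between the standard groups is argued against at 48 h, where salt against standard 48 h alone gave 101 genes in the epidermis, 100 in the cortex, 71 in the endodermis and 99 in the stele (at 1 h against standard 1 h alone 1, 0, 0 and 8), while 3 to 32 h have no standard arrays. RNA quality stays open, since the actin control lay above all standard arrays in the cortex at 32 and 48 h and in the epidermis at 48 h. No control lay apart in the epidermis at 32 h (101 genes). In the stele at 48 h (100 genes) the actin difference was also raised, at 3.93 ± 0.20 against 3.43 ± 0.32, with overlapping arrays. A response to salt may also account for the rise, which was found and tested on the same data and whose list test was not called.

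Root hair genes were at least as high in the stele arrays as in the epidermis arrays. Epidermal cells like those of the epidermis sort would bring the other transcripts of that sort to the stele arrays too. The 359 genes higher in the epidermis than in the cortex and endodermis had a median stele minus epidermis difference of -1.51 (quartiles -2.22 and -0.75). That difference was 0.83 for EXPA7, 1.12 for EXPA18 and 0.92 for XTH26. However, the 359 genes were chosen with the same epidermis arrays, so a lower level in the stele is partly built in. The root hair genes themselves were not called higher in the epidermis (excess -0.24 for EXPA7, -0.12 for EXPA18 and 0.54 for XTH26). The 359 genes may therefore not stand for hair cells, whose presence in the stele sort they do not test. In the median they were 0.25 higher in the stele than in the cortex and endodermis. Whether some epidermal cells were in the stele sort therefore stays open. Free RNA of hair cells in every sort would give like levels everywhere, while the range of EXPA7 over the 4 types was 0.904 and the stele exceeded the cortex and endodermis by 0.89 in EXPA7, 1.498 in EXPA18 and 2.20 in XTH26. Unequal amounts of free RNA stay open, since the spread was wide (for XTH26, SD 1.17 in the stele and 1.53 in the epidermis) and the bound of 3 set for EXPA7 was not reached. Expression of these genes in stele cells was not tested and could also account for the pattern.

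In the endodermis at 1 h of salt, falls outnumbered rises (629 against 191). RNA degradation would raise the 3′ minus 5′ difference of all control transcripts. These disagree, since the actin difference moved by -0.0377 (SE 0.08) while GAPDH moved by 0.95 (SE 0.07) and ubiquitin by 0.17 (SE 0.03), so degradation stays open. Scaling between arrays raised the share of rises from 23.3% to at most 38.4% (Wilson 95% interval 35.1 to 41.9), an interval that spans the bound of 40 set for this test. It treats genes as independent, which genes read on the same arrays are not, so it is likely too narrow. How much of the imbalance may come from scaling is open, and an early repression by salt is also possible.

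Regrouping the arrays shows how far chance could give such counts. In each of the 24 salt comparisons, only 1 of the 84 splits of the 9 arrays, the real one, gave as many genes (535 to 2212 real with the 6 standard arrays taken as 1 group, at most 1042 in any other). For the differences among cell types the splits used salt arrays with the standard mean of their type subtracted, without the error of that mean, so the real counts are 1637 to 2562 in place of 1555 to 2514. At each time only 1 of 100 drawn splits reached the real count (at most 1574 otherwise), and the reported count also exceeded the highest other. The same holds for the change over time (1 of 100, 1591 to 2209 real and at most 1358). For the cell type excesses it was 1 of 100 in the epidermis, endodermis and stele and 3 of 100 in the cortex, where another split gave 342 genes against the real 272. The 10 splits of 6 standard arrays are too few for a share under 0.05. There the real counts and the highest others were 136 and 321 in the epidermis (3 of 10 as large), 172 and 0 in the cortex, 167 and 17 in the endodermis and 457 and 225 in the stele (1 of 10 each). The 321 point to a structure among the epidermis standard arrays that does not follow the time on medium.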
